A study of Homo sapiens with 4 samples.

How the data were processed

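The data were 4 Agilent 2-colour whole-genome arrays of 60-base probes, 1 for each of 4 groups: parental H522 cells, and the clone H522Tr-shSOX4-1 at 0, 24 and 96 h after 2.5 µg/ml doxycycline. Per the labels, total RNA was amplified from a T7 promoter primer and labelled with Cy5 for the cells and Cy3 for a commercial human reference pool, with no dye swap, so dye effects specific to a probe cancel in differences between arrays but not in a single log ratio. Amplification of this kind starts at the 3' end of transcripts, so probes far from it depend more on RNA length. Per the file headers, the images were read with Agilent Feature Extraction 9.5.3.1, the probe coordinates are those of genome build hg17, and each file holds 1 array with no pooling. Slide was taken from the files: 2 slides held 2 arrays each, and each slide was a separate scan.

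Per the file headers, the deposited signals are intensity values on a linear scale, given as the mean of a spot with its median local background and also after the scanner software's background and dye correction. Per the file headers, the log ratio and its error are log10 of red over green, and both were converted to log2. The deposited series value table is in log2 units, which its description does not state; each column differed from the scanner log ratio by a constant of -0.35, -0.35, -0.33 and -0.35 for parental, 0, 24 and 96 h. Its column medians were -0.18, -0.09, -0.17 and -0.15, its direction is red over green, genes were not centred, and it has a floor at -6.64. Scale, centring and direction are thus known, and the reason for the constant is not. Each array had 45015 spots, including controls, and 41000 probes, of which 264 were printed on 10 spots each.

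The spot signals were corrected for background with normexp and an offset of 50 and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Later steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The offset draws ratios of dim spots towards 0, so differences of dim genes are understated. Spots marked as outliers were left out (107 to 134 per array) and replicated spots averaged. Probes were named from their accession through the reference gene tables (23845), from the symbol in the files (2018), from a former symbol (966) or kept under the file's own name (1616), and 12555 had no name. A gene was represented by its brightest probe over the 4 arrays, and features had to be well above background in red on at least 1 array, which left 15744 named genes and 8049 unnamed probes.

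With 1 array per group no test across genes can be run. A difference of at least 1 log2 unit (2-fold) was counted by size alone. The error of a difference is the scanner software's error of both arrays, added in quadrature, with a median of 0.23 per array, and covers measurement and not culture. The number of arrays limits the precision. Replicated spots had a median SD of 0.06, 0.06, 0.06 and 0.07 within an array. Genes above background on only 1 of 2 arrays were given a bound: the bright signal over the higher of the lowest signal among probes well above background and the dim probe's own signal, in the red channel after loess and quantile normalization of average intensity, which is open to dye bias.

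Choices fixed before the data were examined were the 2-fold rule, the gene lists, the alternative settings and the rule for named genes. The rule took SOX4 and the 8 highest and 8 lowest named genes in the comparisons of the clone at 0 h with parental cells and of 24 and 96 h with 0 h, 5 and 5 for 96 h against 24 h, 3 and 3 for induced against parental cells, and 10 and 10 by smallest separation of induced from uninduced arrays. These ranked genes, each read at its brightest probe, had to be above background on the arrays compared, free of outlier and saturation marks, and not contradicted in direction by another measured probe, which passed over CCSAP and AKAP12 at 96 h against 0 h. For separation this was judged on the means of the induced and uninduced arrays. The rule also took the 3 largest bounds each way and, for each list, up to 4 members beyond 2-fold or up to 2 abundant examples, with no condition on other probes. Not every gene that the rule took is named in the text or drawn. Genes the reference places on the Y chromosome, and XIST, were left out.

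The 27 gene lists were SOX family, reported SOX4 targets in other systems, neuronal and neuroendocrine, clustered protocadherins, epithelial, mesenchymal and extracellular matrix, DNA replication, mitosis, p53 targets, Notch pathway, Wnt targets, TGF-beta and BMP targets, interferon response, amino acid and integrated stress response, endoplasmic reticulum unfolded protein response, nuclear-encoded oxidative phosphorylation, glycolysis, hypoxia response, cholesterol synthesis, microRNA machinery, immediate early, lung lineage, cancer-testis, cytosolic ribosomal proteins, heat shock, and blood and fibroblast or endothelial markers for other cell types. Each list's median difference was placed among 10000 random lists of the same size drawn from the same 20 intensity bins. These percentiles describe the arrays and are not p-values, since genes on 1 pair of arrays share their error.

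The steps were tested on simulated data, for probes made from the uninduced clone array and for lists on simulated differences for the genes of 96 h against 0 h. Of 50 probes given each log2 change, the 2-fold rule called 70% at -2, 44% at -1.3, 72% at 1.3 and 86% at 2, with median estimates of -1.52, -0.92, 1.12 and 1.63 and 0 false calls among 31169 probes. Only proportional noise and a dye bias were simulated, so the 0 does not measure false calls between real arrays. The measured reference channel alone differed beyond 2-fold for 214 features at 24 h against 0 h and 189 at 96 h against 0 h. It did so for 98 at 96 h against 24 h and 48 in the clone at 0 h against parental cells. Effects shared by both channels of a spot are not removed from those values. Of 200 simulated lists of 20 genes, 8 fell outside the central 95% with no shift, 114 with a shift of 0.1 and 200 with a shift of 0.3. Genes varied independently in this simulation, so these rates do not carry over to lists whose genes vary together.

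The 10 alternative settings fixed in advance were an offset of 10, the scanner software's ratio, median centring, quantile normalization between arrays, the sample channel alone, red above background on all 4 arrays, both channels above background on all 4 arrays, no filter, the median over a gene's probes, and the series value table. A separation threshold of 1.5-fold and the most 3' probe of each gene were added after seeing the data. A fit with slide as a block was not possible, since induced and uninduced arrays share no slide, and no array of the series held parental cells treated with doxycycline.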

Results

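Gene expression was measured in H522, an established human lung adenocarcinoma cell line, and in H522Tr-shSOX4-1, a clone derived from it that carries a doxycycline-inducible short hairpin RNA against SOX4. SOX4 is a transcription factor of the SOX family with roles in progenitor cells and in neural and other development. There were 4 groups with 1 array each: parental cells, and the clone at 0, 24 and 96 h after addition of 2.5 µg/ml doxycycline. There were no replicates, so no value below has an error between cultures, no test was run, and each error is the scanner software's measurement error of the array values. On each 2-colour array the cell line RNA was labelled red (Cy5) and a common human reference pool green (Cy3), and all values are log2 ratios of sample over reference. The number of probes with red signal well above background was 30118 of 41000 in parental cells, 29050 at 0 h, 29438 at 24 h and 29144 at 96 h. The arrays of parental cells and of the clone at 0 h shared a slide, and those at 24 and 96 h shared the other, so induction and slide cannot be told apart.

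SOX4, the gene targeted by the hairpin, was measured by 2 probes of the transcript NM_003107. The first, at chromosome 6, 21704964 to 21705023 (hg17), gave a log2 ratio of 3.46 (error 0.38) in parental cells, 3.43 (error 0.38) in the clone at 0 h, 1.48 (error 0.25) at 24 h and 1.38 (error 0.24) at 96 h. The second, at chromosome 6, 21705980 to 21706039, gave 2.77 (error 0.34), 2.98 (error 0.35), 0.54 (error 0.21) and -0.18 (error 0.20) in the same order. Relative to 0 h, the log2 difference of the first probe was -1.95 (error 0.45) at 24 h and -2.05 (error 0.45) at 96 h, which leaves 25.9% and 24.2% of the 0 h ratio. The second probe differed by -2.44 (error 0.41) and -3.16 (error 0.40), which leaves 18.4% and 11.2%. Between 24 and 96 h the first probe differed by -0.10 (error 0.35) and the second by -0.72 (error 0.30). The uninduced clone differed from parental cells by -0.04 (error 0.54) at the first probe and by 0.21 (error 0.49) at the second, both smaller than the error. The files do not say where in the transcript the probes or the hairpin's target lie. The reference channel at the first probe was higher by 0.62 at 24 h and by 0.75 at 96 h, and the sample channel alone gave differences of -1.33 and -1.30.

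**Figure D1:**
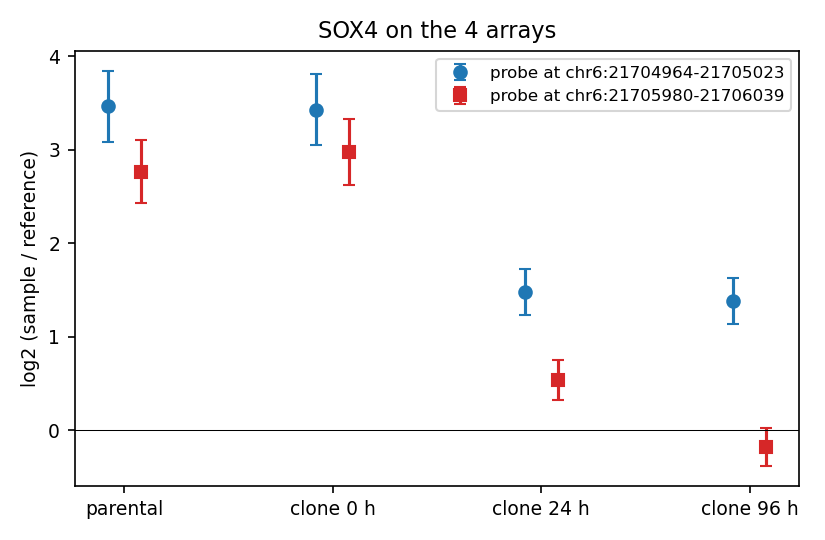
Log2 ratio of sample over common reference for the 2 SOX4 probes on the 4 arrays, 1 array per group, with bars for the scanner software's measurement error. Both probes lie at or above 2.77 in parental cells and in the clone at 0 h, and at or below 1.48 at 24 and 96 h.

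The uninduced clone was set against parental cells to show what the clone differed in before any doxycycline. TPD52L1, which encodes a tumour protein D52 family member, was higher in the clone by 7.28 (error 0.62), and INHBA, the activin A subunit, by 5.77 (error 0.53). HOXD1, a homeobox transcription factor, was higher by 4.92 (error 0.65) and HAPLN1, a hyaluronan link protein of the matrix, by 4.48 (error 0.69). AREG and EREG, ligands of the EGF receptor, were lower, with log2 differences of -5.23 (error 0.51) and -4.06 (error 0.45), as was AGR2, an endoplasmic reticulum protein of secretory epithelium, at -4.25 (error 0.64). In all, 582 genes and unnamed probes were at least 2-fold higher and 392 at least 2-fold lower among 23793 measured, of which 15744 carried a gene name. Among the other genes with the largest differences were GALNT14, a mucin-type glycosyltransferase (4.24, error 0.40), HGF, the MET ligand (4.01, error 0.39), and NFATC1, a calcium-regulated transcription factor (3.99, error 0.46), on the higher side. On the lower side they were ZNF462, a zinc finger protein (-3.97, error 0.62), MDK, the growth factor midkine (-3.58, error 0.51), CEBPD, a stress-responsive transcription factor (-3.43, error 0.38), GRB14, an adaptor of the insulin receptor (-3.42, error 0.41), and SLC16A5, a monocarboxylate transporter family member (-3.26, error 0.49). HGF and NFATC1 each had another measured probe, higher by 3.14 and 1.41.

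Some genes were well above background on only 1 of these 2 arrays and have only a bound, which rests on the sample channel alone and carries no error. KCNJ3, a potassium channel, was at least 7.74-fold higher in the clone and ADAMTSL3, a matrix protein, at least 5.79-fold. RNLS was at least 11.7-fold lower, the long noncoding RNA LINC01549 at least 6.46-fold and TRPM2, a cation channel, at least 6.01-fold. Across all genes the robust SD of the difference was 0.27, and the 2 arrays correlated at r = 0.928 across genes, which are not independent replicates. The number beyond 2-fold was 974 here and 2563 with the scanner software's own ratio.

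Of 27 gene lists, 10 had a median outside the central 95% of 10000 random lists matched on brightness. If genes varied independently 1.35 would be outside, but genes of a list may vary together. Immediate early genes, which respond within minutes to growth signals, had the highest median difference, 0.67 (percentile 100; 0.43 with the sample channel alone), with 14 of 19 measured members above 0. Of these DUSP6, a phosphatase of ERK, was higher by 1.91 (error 0.48), JUN by 1.30 (error 0.48), and KLF2 by 3.15 (error 0.36) at 1 probe but by 0.21 at its other probe. The endoplasmic reticulum unfolded protein response had a median of 0.44 (percentile 100) and no member beyond 2-fold, with the chaperone HSP90B1 at 0.59 (error 0.35) and MANF at 0.57 (error 0.30). The amino acid and integrated stress response had a median of 0.25 (percentile 99.5), and asparagine synthetase, ASNS, was higher by 1.33 (error 0.32) and the pseudokinase TRIB3 by 1.05 (error 0.30). DNA replication genes (median 0.29, percentile 100, 24 of 26 above 0) and mitosis genes (0.19, percentile 98.7, 22 of 26 above 0) had no member beyond 2-fold. MCM7, a helicase subunit, was higher by 0.50 (error 0.29), and CENPF, a kinetochore protein, by 0.34 (error 0.29; other probe 0.06), whereas PTTG1, the mitotic regulator securin, differed by -0.24 (error 0.30).

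Wnt targets had a median of 0.24 (percentile 99.1), with 4 members at least 2-fold higher and 2 lower. AXIN2, a negative regulator of the pathway, was higher by 1.35 (error 0.30) and NKD2 by 1.39 (error 0.34; other probe 0.14), whereas RNF43, a ubiquitin ligase for Wnt receptors, differed by -1.78 (error 0.47) and APCDD1 by -1.44 (error 0.32). Neuronal and neuroendocrine genes had a median of 0.17 (percentile 99.5), although 2 of the 3 members beyond 2-fold were lower: TUBB3, a neuronal tubulin, by a log2 difference of -1.39 (error 0.35) and chromogranin B, CHGB, at -1.31 (error 0.32), against a neurofilament gene, NEFL, at 1.03 (error 0.39).

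Clustered protocadherins, neuronal cell adhesion genes, had the lowest median, -0.73 (percentile 0; -1.10 with the scanner software's ratio), with 24 of 26 measured members below 0 and 7 at least 2-fold lower. PCDHB16 differed by -1.83 (error 0.34), PCDHB7 by -1.43 (error 0.34), PCDHB14 by -1.19 (error 0.34) and PCDHGA8 by -1.16 (error 0.32). Whether each probe reads only the protocadherin it is named for was not tested. Counts of members of this list, here and below, may thus not be counts of independent measurements. Interferon response genes had a median of -0.17 (percentile 0.82; -0.45 with the scanner software's ratio and -0.29 with the sample channel alone), with IFIT1 at -2.20 (error 0.38), IFI35 at -1.58 (error 0.33) and IFI6 at -1.16 (error 0.37), but the RNA sensor IFIH1 was higher by 1.65 (error 0.33). Cytosolic ribosomal proteins had a median of -0.12 (percentile 2.47), which turned to 0.026 with the scanner software's ratio. RPL13 differed by -0.13 (error 0.31) and RPS2 by 0.14 (error 0.31), with other probes on both sides of 0 for each.

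The remaining 17 lists had medians inside the central 95%. Epithelial genes (median 0.05) held both LAMA3, a laminin chain, at 2.08 (error 0.34) and the adhesion molecule EPCAM at -1.23 (error 0.30). Mesenchymal and extracellular matrix genes (0.03) held the collagen IV genes COL4A2 at 2.76 (error 0.54) and COL4A1 at 2.09 (error 0.44), and vimentin, VIM, at -1.14 (error 0.46). The TGF-beta and BMP target list (0.06) had 6 members at least 2-fold higher and none lower, led by INHBA, with CCN1 at 2.71 (error 0.49) and SKIL at 2.23 (error 0.41). The p53 target list (0.14) held PMAIP1, a pro-apoptotic BH3 protein, at 2.02 (error 0.58) and the kinase PLK2 at -2.71 (error 0.58). Notch pathway genes (0.04) held the ligand JAG1 at 1.62 (error 0.38). Hypoxia response genes (0.13) held adrenomedullin, ADM, at 2.52 (error 0.45), with 1.51 in the sample channel alone. Cancer-testis genes (-0.07) held PRAME at -3.15 (error 0.44). Reported SOX4 targets in other systems (0.10) held EGFR at 1.37 (error 0.41) and the histone methyltransferase EZH2 at 1.14 (error 0.30; other probe 0.03), besides TUBB3, and its median turned to -0.12 with the scanner software's ratio.

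The SOX family list (median -0.04) held SOX8 at 2.28 (error 0.36; other probe -0.02). The list of blood markers had a median of -0.01 (-0.13 with the scanner software's ratio), and the list of fibroblast and endothelial markers of -0.05, which became -0.74 with the scanner software's ratio. In the latter list 4 of 12 members were at least 2-fold lower, with TEK, an angiopoietin receptor, at -3.01 (error 0.55), LUM at -1.42 (error 0.63) and DCN at -1.34 (error 0.56), and FAP was higher by 1.51 (error 0.50). Cholesterol synthesis had a median of 0.06, with squalene epoxidase, SQLE, at 1.11 (error 0.34), glycolysis of -0.05, with the phosphofructokinase PFKM at -1.06 (error 0.30), and the microRNA machinery of -0.09, with TNRC6B at -1.07 (error 0.30). Nuclear-encoded oxidative phosphorylation (-0.08), lung lineage (-0.00) and heat shock (0.12) had no member beyond 2-fold.

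**Figure D2:**
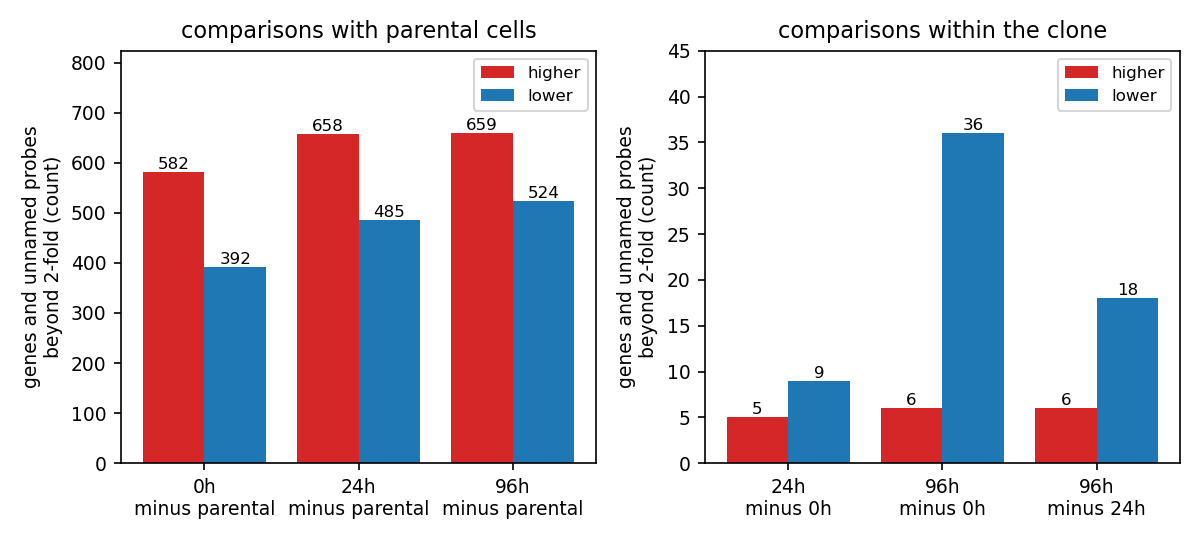
Number of genes and unnamed probes at least 2-fold higher (red) or lower (blue) in each of the 6 comparisons of 2 arrays, out of 23793. Counts lie between 392 and 659 in comparisons with parental cells and between 5 and 36 within the clone, drawn on separate vertical axes.

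At 24 h after doxycycline, few genes differed from 0 h besides SOX4. FKBP7, an endoplasmic reticulum peptidyl-prolyl isomerase, differed by -1.19 (error 0.37), TMSB15A, an actin-binding thymosin, by -1.16 (error 0.30) and the protocadherin PCDHB5 by -1.13 (error 0.39). CD24, a surface glycoprotein, differed by -1.09 (error 0.34), HIPK2, a nuclear kinase that acts on p53, by -1.05 (error 0.41), and SLC6A16, a solute carrier, by -0.99 (error 0.33). DOCK4, a Rac exchange factor, differed by -1.09 (error 0.30), with its other probes at -0.82 and -0.13. Among genes that were higher, HMOX1, heme oxygenase, stood at 0.79 (error 0.29) and CYBRD1, a ferric reductase, at 0.72 (error 0.29; other probe 0.48).

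In all, 5 genes and unnamed probes were at least 2-fold higher and 9 at least 2-fold lower at 24 h. Some genes on the higher side were dim: PDK4, a pyruvate dehydrogenase kinase, differed by 0.82 (error 0.83), SETBP1 by 0.78 (error 0.82) and THBS2, a thrombospondin, by 0.75 (error 1.07), each less than 2 errors. GDAP1L1 differed by 0.73 (error 0.33). SPEM1, a spermatid protein, stood at 1.09 (error 0.36), but its sample channel alone differed by -0.71 and its reference channel by -1.80. The robust SD across genes was 0.17 and the arrays correlated at r = 0.989 across genes. The count of 14 became 78 with a background offset of 10, 53 with median centring, 268 with the sample channel alone and 748 with the scanner software's ratio.

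At 96 h, next to SOX4 at -2.05, the genes with the lowest differences from 0 h included 3 histone genes. The histone H4 genes H4C3, H4C13 and H4C2 differed by -2.03 (error 0.33), -1.78 (error 0.33) and -1.73 (error 0.33). PIK3R3, a regulatory subunit of phosphoinositide 3-kinase, differed by -2.05 (error 0.33), REST, a repressor of neuronal genes, by -1.99 (error 0.32) and the kinase CDK11B by -1.93 (error 0.31). In these 3 genes the other measured probes stood at -0.27 for PIK3R3, at -0.12 for REST and between -0.25 and -0.10 for CDK11B. TCF7L1, a transcription factor of the Wnt pathway, differed by -1.63 (error 0.36) at its measured probe.

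The higher genes at 96 h included PTGER4, a prostaglandin E2 receptor, at 1.26 (error 0.63), and KLF2, a Krüppel-like transcription factor, at 1.03 (error 0.45), whose other probe stood at 0.05. CFI, complement factor I, stood at 1.25 (error 0.77), PLA2G3, a secreted phospholipase, at 0.93 (error 0.42) and SH2D2A, a T cell adaptor, at 0.89 (error 0.38). SPEM1 stood at 1.23 (error 0.39) and TEX13B at 0.87 (error 0.48), with sample channel differences of -0.71 and -0.06. In all, 6 genes and unnamed probes were at least 2-fold higher and 36 at least 2-fold lower. For named genes well above background on only 1 of the 2 arrays, the bounds rest on the sample channel alone, between slides, and carry no error. They reached 2-fold for 37 of 337 genes on the higher side and 9 of 245 on the lower, the reverse of the balance above. By these bounds TNS1, a focal adhesion protein, was at least 4.76-fold higher, GALP at least 3.83-fold and TNFRSF17 at least 3.51-fold. UNC5D, a netrin receptor, was at least 2.51-fold lower, PTGER3 at least 2.49-fold and ACSBG1 at least 2.47-fold. The robust SD was 0.17 and r across genes was 0.987. The count of 42 became 95 with an offset of 10, 88 with median centring, 288 with the sample channel alone and 771 with the scanner software's ratio, and the lower share of 85.7% became 23.3% with the sample channel alone.

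Between the induced times, which shared a slide, the lowest differences among named genes, each at its brightest probe, were those of REST (-1.59, error 0.31), H4C13 (-1.55, error 0.33), CCSAP, a spindle-associated protein (-1.55, error 0.32), H4C3 (-1.51, error 0.32) and PPDPFL (-1.49, error 0.57). The other probe of REST stood at -0.08 and those of CCSAP at -0.08 and -0.06. ROPN1B, a sperm fibrous sheath protein, was higher at 96 h by 1.69 (error 0.43), CFI by 1.23 (error 0.77) and TNRC6C, a microRNA silencing factor, by 0.77 (error 0.30; other probe 0.10). CHD5, a chromatin remodeller, stood at 0.93 (error 0.59) while its reference channel differed by -1.11 and its sample channel by -0.18. In all, 6 genes and unnamed probes were at least 2-fold higher and 18 lower, the robust SD was 0.12 and r across genes was 0.993. Among 25 probes above background on all 3 clone arrays that were at least 2-fold lower at 96 than at 24 h, 15 belonged to a gene with another measured probe. The count of 24 became 85 with an offset of 10, 58 with median centring, 177 with the sample channel alone and 587 with the scanner software's ratio.

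**Figure D3:**
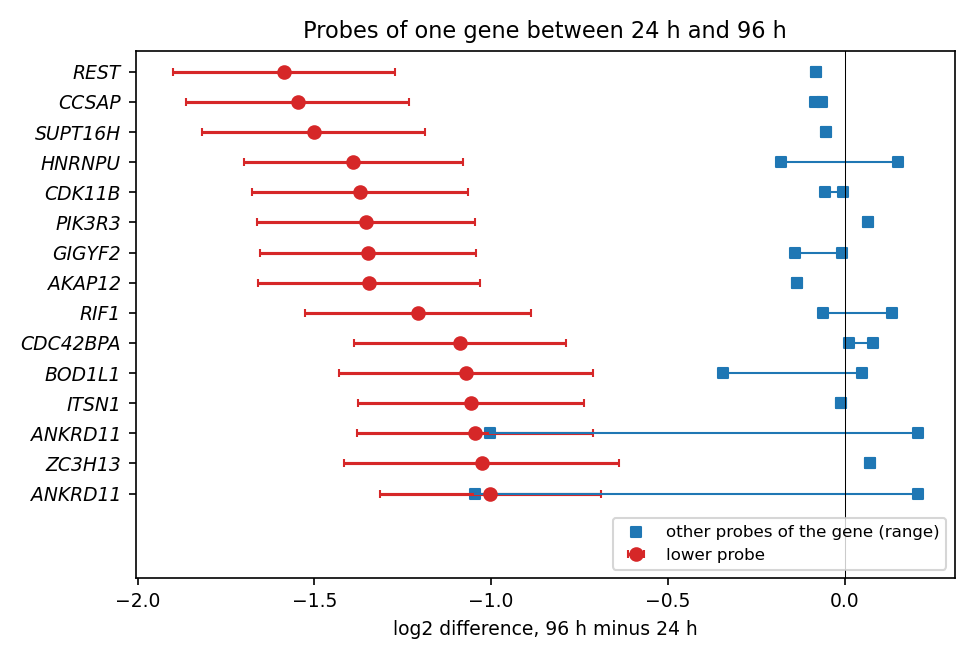
Log2 difference between 96 and 24 h for the 15 probes at least 2-fold lower at 96 h that have another measured probe (red, bars for measurement error) and the range of the other probes of the same gene (blue). Red points reach down to -1.59, and the other probes lie between -0.34 and 0.21, except that ANKRD11 has 2 such probes, each drawn also among the other's blue points.

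Genes that set the induced arrays apart from the uninduced ones were counted as those with both induced arrays at least 2-fold above, or below, both the 0 h and the parental array. None was higher and 5 were lower. Of these 4 were named: SOX4, with a smallest separation of -1.95, CD24 (-1.09), HIPK2 (-1.05) and FKBP7 (-1.02). The remaining 1, singled out after its values were seen, was the unnamed probe A_32_P96752 on the opposite strand between the SOX4 probes, at chromosome 6, 21705752 to 21705811 (hg17), which gave 3.45 in parental cells, 3.81 at 0 h, 1.66 at 24 h and 1.37 at 96 h. The other ways to split the 4 arrays into pairs gave 0 genes each.

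Among other named genes with large separations on the lower side were AUTS2, a neurodevelopmental gene (-0.97; its other probe 0.10 at 96 h relative to 0 h), the protocadherins PCDHB11 (-0.97) and PCDHB2 (-0.87), MYB, a progenitor cell transcription factor (-0.95), DOCK4 (-0.93) and GPC2, a neural glypican (-0.92). On the higher side they included KLF2 (0.85), SH2D2A (0.67), ATF3, a stress-induced transcription factor (0.59), OCLN, a tight junction protein (0.56), SYNGR2 (0.54), RGS9BP (0.52), SYT17 (0.52), NPPC, a natriuretic peptide (0.52), and TRIB3 (0.50). At 96 h relative to 0 h the other probe stood at 0.05 for KLF2, 0.12 for ATF3 and 0.23 for OCLN, and the sample channel alone gave 0.34 for ATF3, 0.09 for OCLN, 0.21 for SYNGR2 and 0.31 for TRIB3. The errors of the differences at 96 h from 0 h were 0.67 for MYB (difference -0.97), 0.62 for OCLN, 0.49 for RGS9BP and 0.49 for NPPC. With a threshold of 1.5-fold, chosen after seeing the data, 57 were lower and 4 higher, against 0 and 1 in all for the other splits. Among the 57 were TUBB3 (-0.65), STMN1, a tubulin-binding protein (-0.76), and PCDHB5 (-0.82) and PCDHB13 (-0.75). The count of 5 became 12 with median centring, 45 with the sample channel alone and 104 with the scanner software's ratio, and with the sample channel alone 15.6% of them were lower. All 10 spike-in controls were higher on the induced slide, by 0.16 at the median, and the robust SD of the reference channel between 0 and 24 h was 0.15, against 0.08 between 24 and 96 h.

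**Figure D4:**
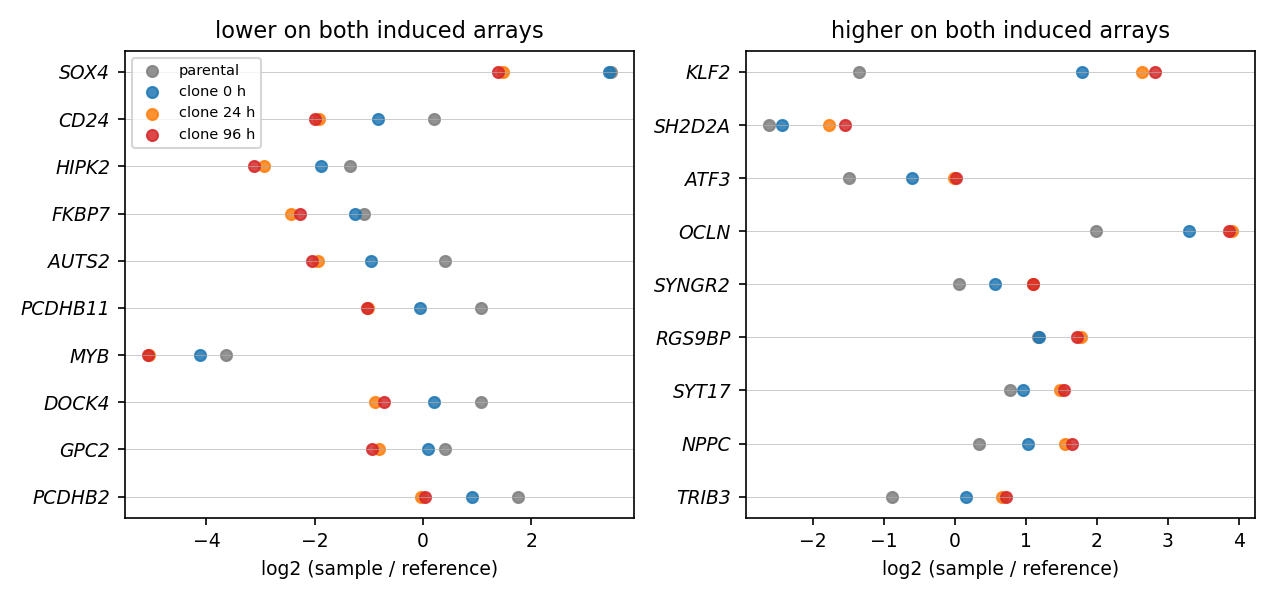
Log2 ratio of sample over reference on the 4 arrays for named genes that part the induced from the uninduced arrays, 1 array per group. SOX4 has the largest gap, with 3.43 or more on the uninduced arrays and 1.48 or less on the induced ones.

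Among the fixed lists, clustered protocadherins were lower after induction, with a median of -0.16 (percentile 0) at 24 h and -0.20 (percentile 0) at 96 h, and 18 and 22 of 26 members below 0. The scanner software's ratio gave -0.55 and -0.60. PCDHB5 was the member beyond 2-fold at 24 h, and PCDHB11 stood at -0.99 (error 0.30) at 96 h. The amino acid and integrated stress response was higher, with 0.16 (percentile 100) at 24 h and 0.14 (percentile 99.6) at 96 h and 19 of 22 members above 0 at each time. TRIB3 differed by 0.50 (error 0.30) at 24 h and ATF4, its main transcription factor, by 0.14 (error 0.30; -0.03 in the sample channel alone). DNA replication stood at -0.08 at both times (percentiles 0.90 and 1.63), and mitosis at -0.11 and -0.09 (percentiles 0.10 and 1.47). MCM7 differed by -0.36 (error 0.29), CENPF by -0.65 (error 0.29; other probe -0.36) and PTTG1 by -0.10 (error 0.31) at 24 h.

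Glycolysis had a median of 0.11 (percentile 98.1) at 24 h, with GPI, glucose-6-phosphate isomerase, at 0.32 (error 0.30) and PGK1 at 0.11 (error 0.32). Mesenchymal and extracellular matrix genes stood at -0.09 (percentile 0.88) and cancer-testis genes at -0.11 (percentile 1.56; -0.06 with the scanner software's ratio and -0.01 with the sample channel alone) at 96 h, and mesenchymal genes at -0.07 (percentile 0.32) between 24 and 96 h. Interferon response genes, which double-stranded RNA can induce, had medians of 0.02 at both times, with ISG15 at 0.23 (error 0.29) and IFITM3 at -0.11 (error 0.53) at 24 h. The reported SOX4 targets in other systems had medians of -0.03 and -0.06 and no member beyond 2-fold, with TUBB3 at -0.76 (error 0.29) at 24 h (other probe -0.18) and EZH2 at -0.33 (error 0.30). Lists outside the central 95% numbered 5 of 27 at 24 h, 6 at 96 h and 1 between the induced times. If genes varied independently 1.35 would be outside. Between 24 and 96 h the arrays shared a slide, and the median spike-in difference there was 0.006, smaller in size than the mesenchymal median. The medians against 0 h are smaller in size than the median spike-in difference between the slides (0.18 at 24 h) except that of the protocadherins at 96 h. Under other settings this did not hold, as for the protocadherins above and, with the sample channel alone at 24 h, for DNA replication (-0.20) and the amino acid response (0.21). The spike-ins had weight 0 in the normalization that centres the gene probes. Their differences therefore do not measure the error of list medians, between slides or within one.

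**Figure D5:**
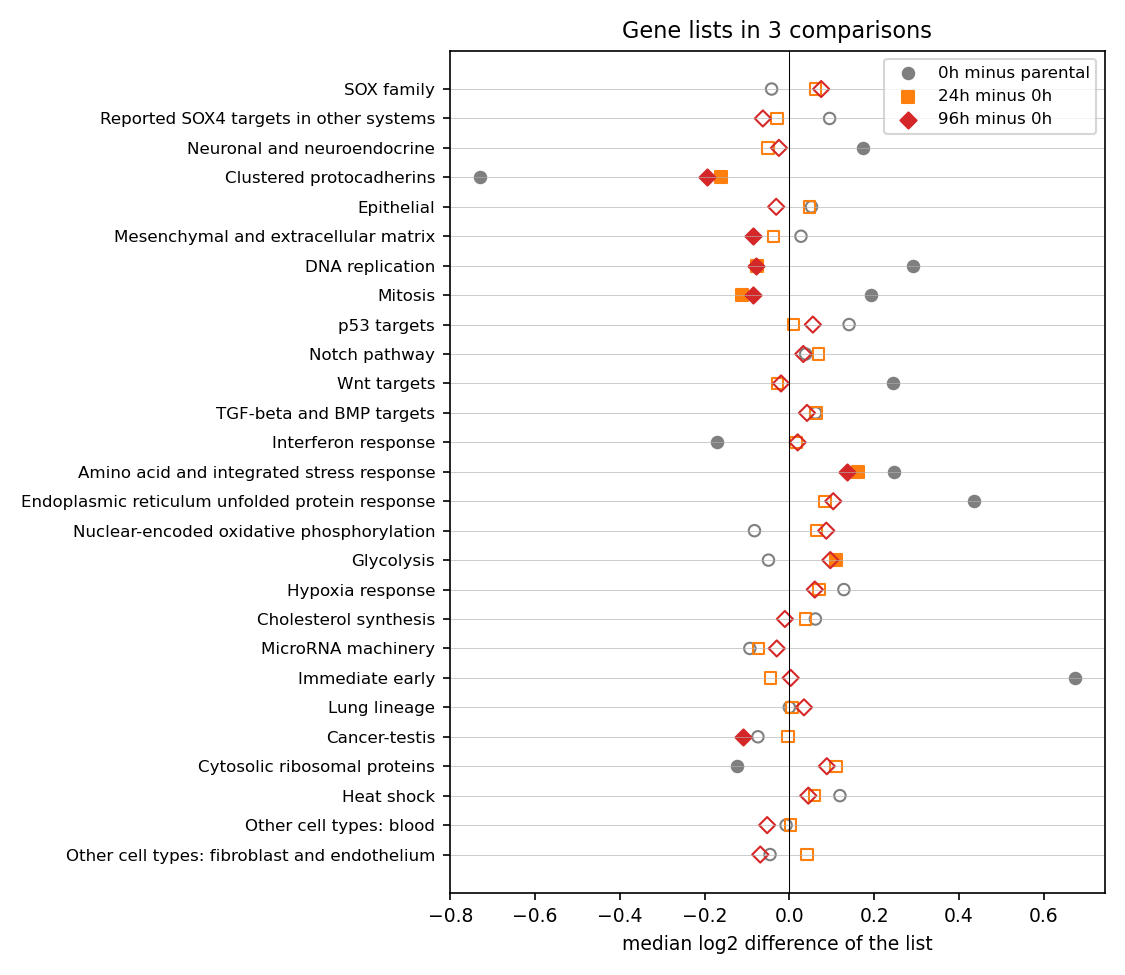
Median log2 difference of each of the 27 gene lists in 3 comparisons, the clone at 0 h against parental cells and 24 and 96 h against 0 h, filled where the median lies outside the central 95% of 10000 random lists matched on brightness. Clustered protocadherins are lowest in the comparison of the uninduced clone with parental cells (-0.73) and in both comparisons with 0 h (-0.16 and -0.20).

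The induced clone was also set against parental cells, which includes the clone's difference before induction. TPD52L1, INHBA and HOXD1 were highest among the genes that met the rule for naming at 24 h (7.37, 5.70 and 4.97, errors 0.62, 0.52 and 0.64) and at 96 h (7.55, 5.66 and 5.03, errors 0.63, 0.52 and 0.66). AREG was lowest at both times, at -5.27 (error 0.51) and -5.28 (error 0.51). ZNF462 stood at -4.09 (error 0.63) at 24 h and -4.20 (error 0.65) at 96 h, NREP, a neuronal regeneration protein, at -3.99 (error 0.61) at 24 h, and AGR2 at -4.55 (error 0.66) at 96 h. SOX4 stood at -1.98 (error 0.46) and -2.08 (error 0.45). In all, 658 genes and unnamed probes were at least 2-fold higher and 485 lower at 24 h, and 659 higher and 524 lower at 96 h. With the scanner software's ratio the totals of 1143 and 1183 became 2836 and 2949.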

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

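The tests of background correction and normalization, of distance from the 3' end, of a shift common to a slide, of technical differences between arrays and of chromosome 8, and the 1.5-fold threshold, were chosen only after the results were seen. A human control probe of the array, AT_ssH_RR_3, which entered no comparison, was well above background on all 4 arrays, and its log2 red over green ratio differed by -1.03 at 96 h and by -0.52 at 24 h from the 2.95 at 0 h. AT_ssH_RR_5 differed by 0.40 and 0.21, and the other 6 such probes by -0.15 to 0.26 at 96 h. The gene behind AT_ssH_RR_3 is not given in the files.

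The first pattern is that of the 25 probes at least 2-fold lower at 96 than at 24 h, whose genes had other probes near 0 where others were measured, except that ANKRD11 had 2 such probes. The tables argue against a local defect of the array, since the distances between these spots lay at percentile 20.6 of random sets, and against background correction and normalization, since the scanner software's ratio gave a median of -1.54. All 15 with another measured probe, 100%, lay upstream of it, against 56.7% of 11794 probes. Distances were taken along the chromosome, introns included, to the most 3' probe of the gene, so they are not lengths of RNA. Among 1094 probes over 20 kb upstream of that probe, 14 (1.28%) were lower by 0.7 or more and 0 higher. The share lower by that much was 0.11% within 1 kb, 0.30% from 1 to 5 kb and 0.79% from 5 to 20 kb. Probes of the pattern itself, such as that of CDC42BPA, lie over 20 kb upstream, so these shares are not independent of the pattern. The share of all probes had to be under 50% for the test on the 15 probes to argue for distance from the 3' end, which it was not. Among several probes of a gene all but the most 3' lie upstream of another, so that share could not fall under 50%. The test could thus not decide, and distance from the 3' end stays open. Labelling, a change in transcript ends and RNA integrity at 96 h all stay open, and the design has no second 96 h array to part them. The H4 genes have 1 measured probe each and could not be placed in this way.

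The second pattern is the 57 genes and unnamed probes that were at least 1.5-fold lower on both induced arrays, SOX4 among them. The 10 spike-ins were higher on the induced slide by 0.16 at the median. The normalization removes a shift common to all gene probes of an array, so the spike-ins do not test such a shift. After it, the median difference from 0 h over all features was 0.008 at 24 h and 0.010 at 96 h. The reference channel differed by -0.041 at the median where the sample channel differed by -1.05, and 50 of the 57 remained lower on both induced arrays with the sample channel alone, 42 of them by at least 1.5-fold. With the median of a gene's probes 40 kept that size, but 22 of these genes had another measured probe, and a feature with a single probe cannot change under that setting. For the 22 genes with another measured probe, the other probes argue against errors of single probes. Of these 19 of 23 (82.6%, exact 95% interval 61.2 to 95.05) were lower on both induced arrays, against 22.8% of all such probes. The interval treats probes of the same arrays as independent. Features without another measured probe, CD24, HIPK2 and FKBP7 among them, were not tested in this way. What stays open is the hairpin's effect on SOX4, effects of doxycycline, time in culture and effects of the slide that differ between genes, which may each contribute, since induction and slide cannot be told apart and the series holds no doxycycline-treated parental array.

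The third pattern is the 974 genes and unnamed probes beyond 2-fold between the uninduced clone and parental cells. The spike-ins differed by at most 0.088 between the 2 arrays, on their shared slide. Each spike-in value is a median of 32 spots, so it does not measure errors of single spots. The reference channel alone differed beyond 2-fold for 48 features between these arrays. Broad copy number blocks are not the whole cause, since medians of the 50 nearest genes lay only between -0.45 and 0.71. After that median was subtracted, 86.2% of 961 with a position stayed beyond 2-fold. Blocks much narrower than 50 genes would hardly move such a median, so they were not tested. On chromosome 8, 77.3% of 840 genes were higher in the clone, against 48.4% elsewhere, which restates the difference and does not test extra copies. Clonal selection, the vector and culture history stay open and untested, with 1 clone and 1 array each.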

How the results depend on the processing

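The tests with a separation threshold of 1.5-fold and with the most 3' probe of each gene were chosen only after the results were seen. SOX4 was lower at 24 and 96 h than at 0 h under all settings run, with sizes that moved by more than the error for the sample channel alone (-1.33 and -1.30) and, at 96 h, for the median of its probes (-2.60). With an offset of 10, 24 h against 0 h gave 78, 96 h against 0 h 95 and 96 h against 24 h 85 genes and unnamed probes beyond 2-fold, with 41.0%, 63.2% and 55.3% lower. Median centring gave 53, 88 and 58, the last pair with 61.4% and 55.2% lower. The sample channel alone gave 268, 288 and 177, with 15.7%, 23.3% and 45.2% lower. The scanner software's ratio gave 748, 771 and 587 (44.4%, 50.1% and 56.7% lower), and the deposited series values 702, 740 and 566 (43.4%, 50.9% and 58.1% lower). For the clone at 0, 24 and 96 h against parental cells these last settings gave 2563, 2836 and 2949 (52.8%, 53.8% and 54.8% lower), and 2517, 2801 and 2910 (52.4%, 52.6% and 54.6% lower), where the reported shares were 40.2%, 42.4% and 44.3%. Genes parting induced from uninduced arrays numbered 104 and 94 with them (67.3% and 69.1% lower), 12 with median centring, 45 with the sample channel alone (15.6% lower) and 61 at 1.5-fold, the last by the construction of a wider threshold. A smaller or absent offset draws dim ratios less towards 0, and the cause of the other moves was not tested. SPEM1 turned to -0.71 at 24 h and -0.71 at 96 h with the sample channel alone, and the ribosomal protein list in the uninduced clone to 0.026 with the scanner software's ratio and 0.029 with the deposited series values; the cause was not tested. Of the named gene values under other settings, 687 stayed within the error and the others moved by more. In all, 4 changed sign, each with the sample channel alone: those 2 of SPEM1, which had been beyond 2-fold, and TEX13B at 96 h (-0.06) and CHD5 between 24 and 96 h (-0.18), which had not. Of the list medians 790 stayed within the spread of random lists and the others moved by more. In all, 114 list medians changed sign, of which only the 2 of the ribosomal list had been outside the central 95%. With filters on all 4 arrays, no filter, the median of a gene's probes and the most 3' probe, the 2-fold counts stayed within 1.5 times, but the lower share moved from 64.3% to 75% at 24 h with either filter, and from 75% between 24 and 96 h to 88.9% and 88.2% with the filters and 63.2% with the most 3' probe. Quantile normalization between arrays acts on average intensity and leaves log ratios as they were, so it gave no value, and no fit with slide as a block could be made. No paired analysis was possible because each group had 1 array. Signal over background limits the dim genes, since 29050 to 30118 of 41000 probes were well above it in red.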

Other observations

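The look at chromosome 8 and the choice of histone families were made only after the values were seen. Histone genes differed by family between the uninduced clone and parental cells. H2B genes had a median of -0.90, with 17 of 17 below 0 and a range from -1.02 to -0.75, and H2A genes a median of -0.28, with 15 of 15 below 0. H1 genes had a median of -0.21, whereas H3 and H4 genes lay at -0.01 and -0.04, the latter at -0.25 with the scanner software's ratio. For H2B that ratio gave -0.94 and the sample channel alone -0.96. Histone genes of a family are close in sequence, so their probes are not independent measurements. At 96 h against 0 h, 4 of 12 H4 genes were at least 2-fold lower, H4C4 with -1.35 besides H4C3, H4C13 and H4C2, and no gene of the other 4 families was. H3 genes had a median of -0.28 at 24 h against 0 h, which turned to 0.06 with the sample channel alone.

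Genes of chromosome 8 had a median difference of 0.27 between the uninduced clone and parental cells, at percentile 100 of random sets, while the medians of the other 22 chromosomes lay between -0.06 and 0.03. On chromosome 8, 88 genes and unnamed probes were at least 2-fold higher and 2 lower. The median was 0.40 with the scanner software's ratio, 0.29 with the sample channel alone and 0.01 between 24 and 0 h. Of its genes 77.3% were higher in the clone. No DNA was measured, and whether the clone carries extra copies was not tested.

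The unnamed probe on the strand opposite to SOX4 differed by -2.15 (error 0.50) at 24 h and -2.44 (error 0.50) at 96 h from 0 h, close to the SOX4 probes on either side of it. Whether it reads an antisense transcript or SOX4 itself was not tested.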
